A study of Mus musculus with 2 samples.

How the data were processed

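RNA sequencing of CE1-4, a prostate cancer line of mouse origin, was analysed from 1 untreated library and 1 library of cells treated with prostaglandin E2 (PGE2) for 6 h. Per the labels' protocols, total RNA was purified on silica columns and made into stranded total RNA libraries with an Illumina kit used at its low-input setting. Stranded total RNA libraries hold noncoding and unspliced RNA as well as messenger RNA. The submitters' processing notes name Trimmomatic, TopHat2, Bowtie and HTSeq and the mouse genome build mm10. The tools' versions, the gene annotation and the strand setting of the counting are not given in the sources used here.

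The deposited table holds raw read counts, whole numbers per gene symbol with no normalization by the authors, for 23420 symbols in 1 column per library. Each column was tied to its sample by its name, which repeats that sample's title. The untreated library held 16908429 counts and the treated library 17582808. At this depth 1 CPM (counts scaled to a common library size) stood for 16.9 counts in the untreated and 17.6 counts in the treated library, and a gene with 0 counts could still lie at up to 0.178 or 0.170 CPM, taken as 3 counts. How reads shared by near-identical genes or by overlapping genes were assigned is not given, so values of replication-dependent histone genes, ribosomal protein genes, placental prolactin family genes and overlapping or antisense genes are uncertain beyond their counting error.

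The counts were scaled by edgeR 4.0.16 in R 4.3.3 with the trimmed mean of M values (TMM), which gave factors of 0.997 for the untreated and 1.003 for the treated library. For each gene the log2 ratio of treated over untreated CPM was computed with a prior of 0.5 counts, with a 95% Clopper-Pearson interval from the counts of both libraries. Levels in CPM have exact 2-sided 95% Poisson intervals, except that a gene with 0 counts is given the limit of 3 counts above, which is a 1-sided bound at about that level and lies below the 2-sided bound of 0.219 CPM untreated and 0.209 CPM treated for Ptger3 and Prl. All of these intervals cover counting error only. With 1 library per group the difference has no replicate check, so no p-value was computed and the ratios compare these libraries, not the conditions. A gene was tested if it reached 1 CPM in at least 1 library, which 11387 genes did. It passed the size rule if its ratio was at least 2-fold and its interval excluded 1.

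There were 38 gene lists fixed before the data were examined, with 965 members, of which 950 matched a row of the table, 1 of them through a synonym in the RefSeq gene table of GRCm38.p6. The 13 members of the mitochondrially encoded list matched no row. The median log2 ratio of each list with at least 3 tested members was set among the medians of 10000 random lists of the same size, matched on mean expression in 10 bins. A list stood apart if its median lay outside the central 95% of the random lists. This describes the pair of libraries and is not a test between conditions, and genes of a list are not independent replicates. Coordinates and transcript sequences are from GENCODE release M21 on GRCm38, the assembly also called mm10. GC content and length were found for 99.3% of the tested genes.

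The genes to be named were also set beforehand. They were up to 12 genes per direction past the size rule with the nearer interval bound farthest from a ratio of 1, leaving out unnamed models and clones, small RNA genes and pseudogenes. Up to 4 members past the size rule were added from each list that stood apart and from the PGE2, prolactin, cAMP, EGF receptor and inflammatory lists. Ptgs2, Ptger1, Ptger2, Ptger3, Ptger4, Prl, Prlr, Nr4a1, Fos, Crem, Pde4d, Areg, Vegfa and Il6 were named whatever their values. The size rule left 4 named genes in the higher direction, and no member of those lists past it. The clone A630020A06 was counted among the unnamed models after its values had been seen. Every other gene below was chosen after its values were seen, in each list mostly as a member whose interval excluded 1 or as an abundant member. The values of 1 list member are not reported here.

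The procedure was tested on simulated counts for the same genes and depths, with 200 genes changed by known folds in each simulation. With counting error alone, the size rule found 49 of 50 genes changed 4-fold, 49 of 50 changed 3-fold and 25 of 50 changed 2-fold among 11374 tested genes. In 20 simulated pairs of libraries with no change at all, between 20 and 39 genes passed the size rule. In a further simulation with no change and counting error alone, 0 of 34 lists stood apart. In another, a shift of 0.1 in log2 placed on the G2 and M phase list gave a median of 0.101. These list simulations held neither the spread beyond counting error nor the trend on GC content of the real libraries. They therefore do not show how often lists stand apart for such reasons.

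Alternatives fixed beforehand were total-count, upper-quartile and DESeq2 1.42.0 size factor scaling, a prior of 5 counts, no minimum and a minimum of 5 CPM, a 1.5-fold size, stricter intervals, leaving out unnamed and small RNA rows, and subtraction of lowess trends on abundance or on GC content and length. For the lists they were the mean, other minimums, unmatched random lists, both trends and the leaving out of shared members. Scaling on totals without Rn45s, Lars2 and Malat1, random lists matched on GC content as well, and another random draw were chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 was used for these steps.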

Results

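Transcript levels were measured by stranded total RNA sequencing in CE1-4, a mouse prostate cancer cell line, without treatment and after 6 h with PGE2, a lipid mediator made by way of the cyclooxygenases. Each group was 1 library, with 16908429 counts for the untreated cells and 17582808 for the treated cells. The series title places the comparison in a study of COX-2, the product of Ptgs2, in prolactin signaling between tumor and stroma. The question asked of these libraries was which transcripts differ in the cells after exposure to PGE2. There was no replicate of either group, so none of the differences below has a replicate check. The treatment labels name no vehicle and no PGE2 dose, and give no time for the untreated cells. An effect of a vehicle or of time in culture therefore cannot be told apart from one of PGE2.

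The treated and untreated CE1-4 libraries were close to each other. Of 11387 tested genes, 8136 (71.4%) lay within 1.1-fold and 11125 (97.7%) within 1.5-fold between the libraries, and the median log2 ratio was -0.0014. For 10519 genes (92.4%) the counting interval excluded a 2-fold difference in both directions. For 1396 genes (12.3%) it excluded a ratio of 1, with 753 above and 643 below it. Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, was the 1 gene that reached 5 CPM in a library and passed the size rule. It had 75505 counts in the untreated and 18082 in the treated library, 4478 CPM (4446 to 4509.8) against 1026 CPM (1011 to 1041), a log2 ratio of -2.13 (-2.15 to -2.10). Lars2 lies on chromosome 9 from 123366927 to 123462666 on the plus strand.

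The size rule was passed by 35 genes, 6 higher and 29 lower in the treated library. Apart from Lars2, these genes were scarce, with between 21 and 66 counts in both libraries together. The named genes that were higher were Hist1h4h, a histone H4 gene (21 and 45 counts, log2 ratio 1.02, interval 0.26 to 1.86), Pcsk6, a proprotein convertase (1.10, 0.18 to 2.15), Ccdc28b (1.22, 0.15 to 2.48) and Gk5 (1.01, 0.08 to 2.06). The lower genes included Tfpi, the inhibitor of the tissue factor pathway of coagulation (34 and 10 counts, log2 ratio -1.78, interval -3.01 to -0.78), Ednra, an endothelin receptor (-1.65, -3.19 to -0.44), and Pycard, the inflammasome adaptor (-1.33, -2.78 to -0.14). The transcription regulators Zfp703 (-1.65), Tfcp2l1 (-1.16) and Trerf1 (-1.24) were lower as well, as were the matrix protein genes Ecm2 (-2.02) and Fmod (-1.15). Dnajb3 (-2.03), Sptb (-1.31) and Klhdc8b (-1.73) completed the lower genes named by the rule. In 20 simulated pairs without any change, scaled on total counts, 20 to 39 genes passed, 7 to 20 as higher and 9 to 22 as lower. Under that scaling 33 genes passed in the real libraries, within what counting error gave. Of these, 7 were higher, at the lower end of the simulated range, and 26 were lower, above it. With a coefficient of variation of 2.5% added between the libraries, 7 to 24 genes passed as higher, 10 to 25 as lower, and 1304 to 1418 had an interval that excluded 1, against 1396 observed. With 10% these numbers were 15 to 31, 15 to 33 and 4513 to 4715. The spread beyond counting error in these same libraries was 2.40 to 2.60% for genes with at least 1000 counts. The match at 2.5% is therefore not an independent check. For genes with 30 to below 100 counts, nearer to those past the rule, the spread was 5.82%, and no simulation was run at that setting. The 26 lower genes lay inside the range of 15 to 33 simulated at 10%. At a minimum of 5 CPM 1 gene passed, Lars2, and after subtraction of a trend on abundance 11 genes passed as higher and 21 as lower.

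**Figure D1:**
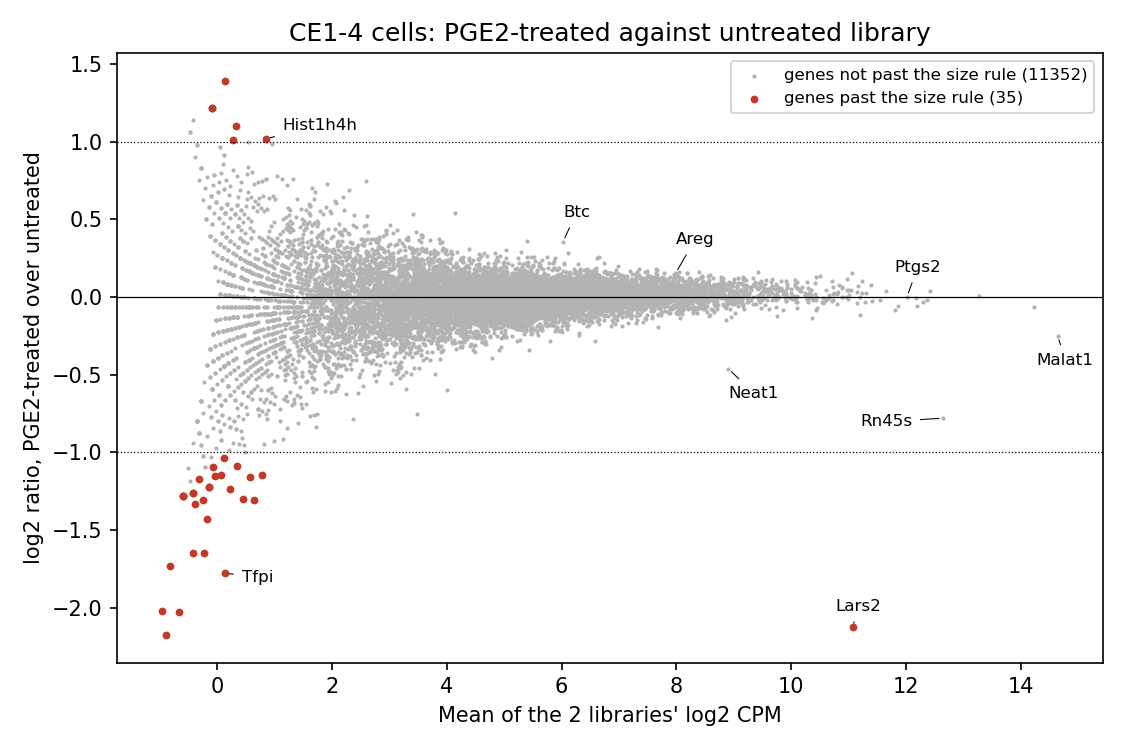
Log2 ratio of the PGE2-treated over the untreated library (vertical axis) against the mean log2 CPM of both libraries (horizontal axis) for each of the 11387 tested genes; red points are the 35 genes past the size rule and dotted lines mark 2-fold. The red points lie at low abundance except Lars2, at a log2 ratio of -2.13.

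Of the 21 genes of PGE2 synthesis, transport and reception, 13 reached 1 CPM in at least 1 library. Ptgs2, encoding COX-2 (chromosome 1, 150100031 to 150108227), had rank 11 of all genes in the untreated library, with 4133 CPM untreated and 4135 CPM treated, a log2 ratio of 0.00090 (-0.014 to 0.016). Among the receptors of PGE2, Ptger4, encoding EP4 (chromosome 15, 5206661 to 5244187), was the most abundant at 25.6 CPM (23.2 to 28.1) and 27.9 CPM (25.5 to 30.5), a log2 ratio of 0.13 (-0.06 to 0.32). Ptger1 had 25 and 30 counts and Ptger2 1 count in each library. Ptger3 had 0 counts in both, which allows up to 0.178 CPM untreated and 0.170 CPM treated, taken as 3 counts. Ptges, a terminal PGE2 synthase, had 10 and 7 counts, whereas Ptges3, the cytosolic synthase also known as a chaperone partner, was at 650.3 CPM untreated with a log2 ratio of 0.16 (0.13 to 0.20). The 13 tested members of the PGE2 list had a median log2 ratio of 0.012, at percentile 57.2 of the random lists. For 12 of them the interval excluded a 2-fold difference in both directions.

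Prolactin itself and its receptor were near or below detection in these cultured cells. Prl had 0 counts in both libraries, with the same upper limits as for Ptger3, and Prlr had 13 and 7 counts (log2 ratio -0.91, -2.52 to 0.47). Genes acting after the receptor were measured, among them Jak2 (213 CPM untreated, log2 ratio 0.07, 0.0033 to 0.13) and Stat5a (104 and 142 counts, 0.38, 0.0099 to 0.76). Elf5, an epithelial transcription factor induced by prolactin in the mammary gland, had 86 and 63 counts (-0.51, -1.01 to -0.03). The median of the 9 tested members was 0.049, at percentile 86.4.

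Ligands of the EGF receptor were higher in the treated library for 3 of the 11 tested members of that list, by small ratios with narrow intervals, and no member had an interval below 1. Areg, encoding amphiregulin, had 4057 and 4713 counts (log2 ratio 0.15, 0.09 to 0.21), Ereg, encoding epiregulin, 3196 and 3773 (0.18, 0.11 to 0.24), and Btc, encoding betacellulin, 972 and 1300 (0.36, 0.23 to 0.48). These 3 genes lie near each other on chromosome 5, with Ereg from 91074622 to 91093646, Areg from 91139599 to 91148432 and Btc from 91357261 to 91402994. Egfr was at 381 CPM untreated with a log2 ratio of -0.03 (-0.08 to 0.02). These intervals cover counting error only. Among genes with 3000 to below 10000 counts in both libraries together, as Areg and Ereg, log2 ratios had a standard deviation of 0.065. With 1000 to below 3000 counts, as for Btc, it was 0.089. The list as a whole had a median of 0.023, at percentile 71.0 of the random lists.

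**Figure D2:**
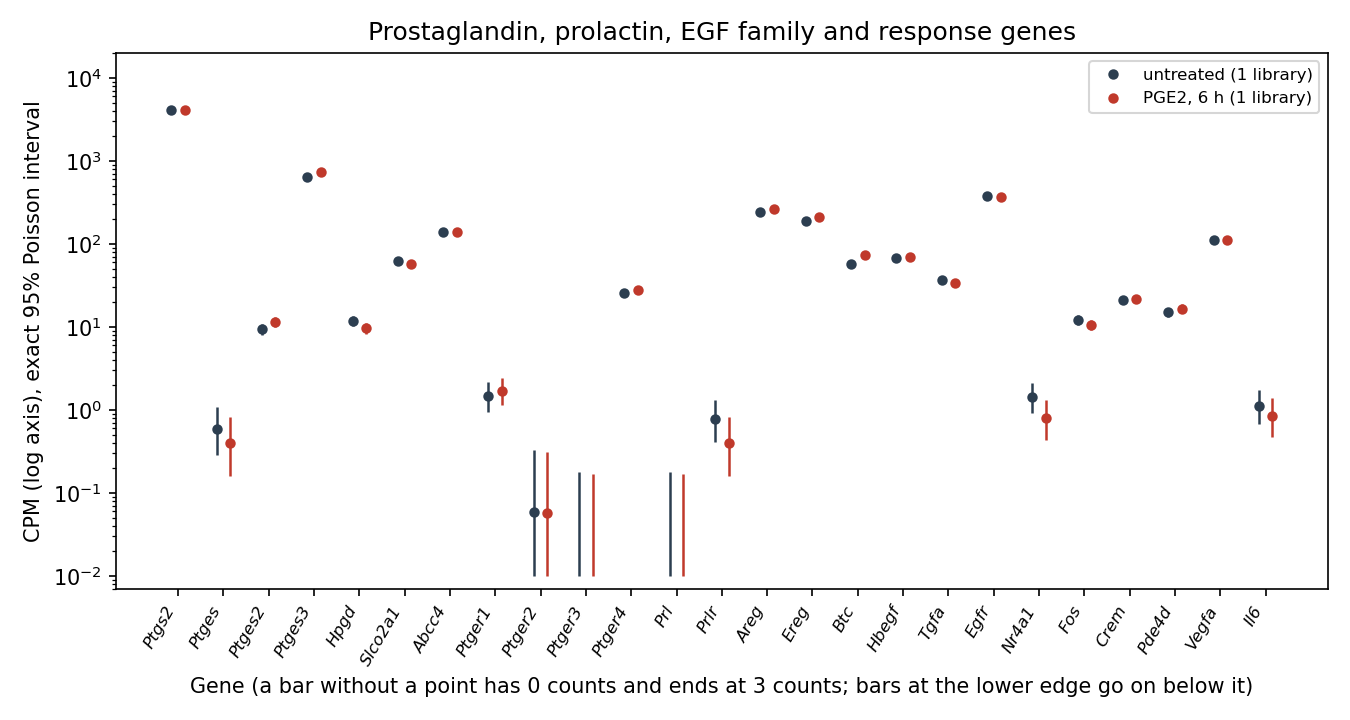
CPM on a log axis for genes of prostaglandin synthesis and reception, prolactin signaling, the EGF family and early responses in the untreated (dark) and PGE2-treated (red) library, with exact 95% Poisson intervals covering counting error only; a gene with 0 counts has a bar up to 3 counts and no point. Ptgs2 lies at 4133 and 4135 CPM, and Ptger3 and Prl had 0 counts in both libraries.

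Of the 34 lists with at least 3 tested members, 8 stood apart from random lists, 2 above and 6 below them, against 1.7 expected by chance. Of these 8, 2 also stood apart by the mean, 4 with no minimum on expression, 4 with unmatched random lists and 4 after subtraction of GC and length trends. The genes of G2 and M phase were higher, with a median log2 ratio of 0.099 over 30 tested members, above all 10000 random lists. Over all 11387 tested genes, 753 had an interval above 1 and 643 below 1, shares that are not matched on abundance. Of the 30 members of this list, 25 had a ratio above 1 and 12 an interval above 1, and none had an interval below 1. The examples include Cenpf, a kinetochore protein (log2 ratio 0.18, 0.10 to 0.25), Kif11, a spindle motor (0.16, 0.10 to 0.21), Top2a, a topoisomerase (0.10, 0.06 to 0.14), and Mki67, the proliferation marker (0.09, 0.03 to 0.14). Plk1 (-0.04) and Aurka (-0.04) had intervals that included 1. Counting intervals narrow as counts rise, so abundant genes exclude 1 more readily. In the more abundant cytosolic ribosomal protein list, with a median near 0, 10 of 48 members had an interval above 1 and 6 below. In the list of S phase and DNA replication, 2 of 30 members had an interval above 1, among them Pcna (0.16, 0.09 to 0.22), and 1 had an interval below 1. That list's median of 0.038 was at percentile 96.6, inside the central 95%.

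Regulators of G protein signaling and phosphodiesterases were the other list on the higher side, with a median of 0.067 at percentile 98.8. Each of its 26 tested members had an interval that included 1. Rgs4 had 351 and 415 counts (log2 ratio 0.18, -0.03 to 0.39) and the cAMP phosphodiesterase Pde4d 254 and 294 (0.15, -0.10 to 0.39). With no minimum on expression the median was at percentile 96.1, inside the central 95%.

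Inflammatory cytokines, chemokines and NF-kB target genes were lower, with a median of -0.108 over 22 tested members at percentile 0.49. Of these, 16 had a ratio below 1, and 2 had an interval below 1. Those were the chemokine genes Ccl7 (520.1 CPM untreated, log2 ratio -0.13, -0.18 to -0.09) and Ccl2 (269.7 CPM, -0.11, -0.17 to -0.05). Il33, encoding an alarmin cytokine, had an interval above 1 (0.12, 0.04 to 0.20), and Il6 had 19 and 15 counts (-0.39, -1.49 to 0.65). The mean of the list was at percentile 17.8, inside the central 95%.

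Extracellular proteases and their inhibitors were lower, with a median of -0.069 over 18 members at percentile 0.17, and 6 of them had an interval below 1. The stromelysin gene Mmp3 had 74 and 43 counts (log2 ratio -0.84, -1.42 to -0.29) and the metalloproteinase inhibitor gene Timp2 was at 895 CPM untreated (-0.12, -0.15 to -0.09). TGF-beta target genes had a median of -0.047 over 23 members at percentile 0.90, with 5 intervals below 1. Id3 (log2 ratio -0.18, -0.31 to -0.05) and Thbs1, encoding thrombospondin 1 (4777 CPM untreated, -0.06, -0.07 to -0.04), were among them. Among genes with at least 10000 counts in both libraries together, without Lars2, Rn45s, Malat1 and Neat1, the log2 ratio had a standard deviation of 0.054. The ratio of Thbs1 was near that spread. Over all 11387 tested genes, 643 had an interval below 1, a share that is not matched on abundance. The TGF-beta list was inside the central 95% by the mean (percentile 6.58), with unmatched random lists (6.50) and after subtraction of trends on GC content and length (6.66). The protease list was inside it by the mean (2.52), with unmatched random lists (2.76) and with no minimum on expression (5.82).

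Genes known to respond to cAMP, the second messenger raised by EP4, had a median of -0.069 over 24 tested members at percentile 2.38. In 20 further random draws this list stood apart in 6. It was inside the central 95% by the mean (percentile 17.2), with no minimum (9.82), at a minimum of 5 CPM (5.54), after subtraction of the abundance trend (3.70) or of the GC and length trends (4.03), and without shared members (17.6). The members named beforehand were Nr4a1 (24 and 14 counts, log2 ratio -0.82, -1.91 to 0.17), Fos (204 and 186, -0.20, -0.49 to 0.10), Crem (353 and 382, 0.05, -0.16 to 0.26), and Pde4d and Areg, given above. All of them except Areg had an interval that included 1. Fosb had 112 and 83 counts (-0.49, -0.92 to -0.07), and Areg was the 1 member with an interval above 1. For 20 of the 24 members the interval excluded a 2-fold difference in both directions. Vegfa, an angiogenic factor of the hypoxia list, was at 112 CPM untreated and 113 CPM treated (0.02, -0.07 to 0.11).

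The remaining lists that stood apart were of abundant, steadily expressed genes with medians near 0. Housekeeping reference genes had a median of -0.019 at percentile 2, with Actb at -0.04 (-0.05 to -0.02), B2m at -0.20 (-0.32 to -0.07) and Hprt at 0.13 (0.08 to 0.18). That list was inside the central 95% with the mean (percentile 2.72), with no minimum (2.58), with unmatched random lists (25.1), after subtraction of GC and length trends (11.6) and with matching on GC content, chosen after seeing the data (8.46). The 48 cytosolic ribosomal protein genes had a median of -0.0068 at percentile 0.45 and a mean of 0.0033. The other scalings fixed beforehand move all genes nearly alike and put that median between 0.00057 and 0.0011, so no direction is given for it. After subtraction of trends on GC content and length it was at percentile 40.3. The Rn45s row, which holds the ribosomal RNA precursor, had 141575 counts in the untreated and 86196 in the treated library, a log2 ratio of -0.78 (-0.79 to -0.77).

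**Figure D3:**
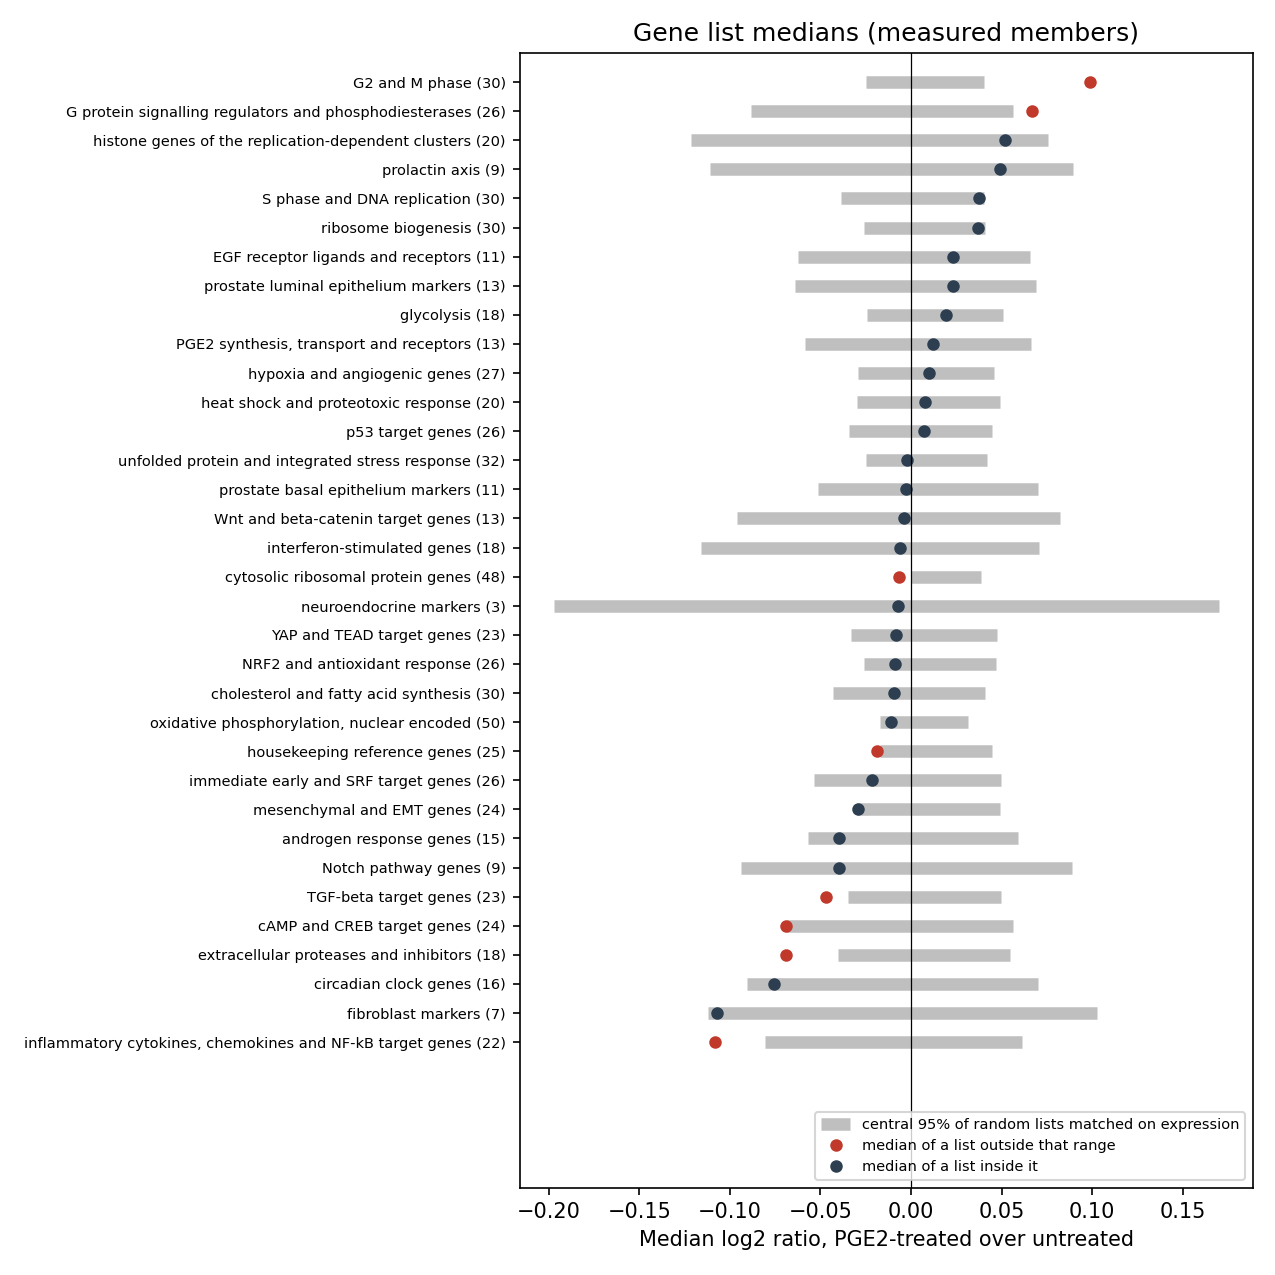
Median log2 ratio of the PGE2-treated over the untreated library (horizontal axis) for the 34 gene lists, with the number of tested members in parentheses; gray bars are the central 95% of 10000 random lists matched on expression, and red points lie outside them. The G2 and M phase list is farthest to the right at 0.099 and the inflammatory list farthest to the left at -0.108.

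Among other lists that lay inside the central 95% were glycolysis (median 0.019, percentile 62.3), hypoxia and angiogenic genes (0.010, 52.2), p53 target genes (0.0071, 52.4), the unfolded protein response (percentile 25.9) and androgen response genes (-0.040, 7.07).

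Of the luminal markers 13 of 21 were tested, with a median of 4.39 CPM untreated over the whole list, and of the basal markers 11 of 20, with a median of 4.00 CPM. Of the mesenchymal genes 24 of 30 were tested, with a median of 59.5 CPM. The luminal keratin genes Krt8 and Krt18 were at 1256 and 758 CPM untreated, with log2 ratios of 0.02 (-0.0041 to 0.05) and 0.04 (0.0028 to 0.07). The basal keratin gene Krt5 had 0 and 2 counts, and Krt14 was at 13.3 CPM untreated. Vim, encoding vimentin, was at 2029.6 CPM and Spp1, encoding osteopontin, at 2495 CPM untreated. The fibroblast list had 7 tested members of 17, among them Col6a1 at 142 CPM untreated, and a median log2 ratio of -0.107 at percentile 3.12, inside the central 95%. The neuroendocrine list had 3 of 15, with Ncam1 at 599 CPM untreated, and a median of -0.0073 at percentile 41.8. Ptprc of leukocytes had 0 and 1 count and Pecam1 of endothelium 0 and 3 counts. The endothelial, leukocyte and erythroid lists had 1, 2 and 0 tested members and gave no median. The luminal list had a median of 0.023 (percentile 70.6), the basal list -0.0025 (32.2, with a median of 0.0053 under scaling on total counts) and the mesenchymal list -0.029 (2.81), each inside the central 95%, with the mesenchymal list outside it in 12 of 20 further random draws.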

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

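With 1 library per group, leaving out a replicate could not be run, and no paired analysis was possible because the groups hold 1 library each. Scaling on totals without 3 abundant genes, matching on GC content and another random draw were chosen after seeing the data. Under total counts, DESeq2 and upper quartile scaling 33 genes passed the size rule, and 36 under totals without Rn45s, Lars2 and Malat1. The median log2 ratio of all genes was 0.0065, 0.0060, 0.0065 and -0.010 under these, outside its binomial interval of -0.0039 to 0.00068 but small. The count of 35 genes (6 higher, 29 lower) became 13 (1 and 12) with a prior of 5, 83 (31 and 52) with no minimum, 1 (0 and 1) at a minimum of 5 CPM and 94 (23 and 71) at 1.5-fold. It became 2 (0 and 2) with the stricter interval level, 1 (0 and 1) where the nearer bound itself had to reach 2-fold, and 20 (4 and 16) without unnamed and small RNA rows. Subtracting the abundance trend gave 11 higher genes. Among the 26 tested genes named beforehand (Ptger2, Ptger3, Prl and Prlr were under 1 CPM and not run), 179 alternative ratios lay within the counting interval and 3 outside it. These were Lars2 (-2.10) after the GC and length trends and Ptgs2 after the abundance (-0.017) and the GC and length trends (-0.039), where the sign of a ratio whose interval included 1 turned. No ratio whose interval excluded 1 changed sign. For many of these genes the interval was far wider than the shifts, as for Tfpi (-1.77 under total counts, interval -3.01 to -0.78). Staying inside it is therefore a weak check.

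The G2 and M phase list stood apart under all 9 alternatives run on it, but not all of these were separate checks. At both other minimums and without shared members it kept the same 30 genes and median of 0.099. Another random draw only repeated the main comparison. With the mean in place of the median, lists that no longer stood apart were the cAMP (-0.074), inflammatory (-0.091), TGF-beta (-0.046), ribosomal protein (0.0033), protease (-0.094) and housekeeping (-0.022) lists, while the immediate early (-0.068), oxidative phosphorylation (-0.022), ribosome biogenesis (0.049) and S phase (0.042) lists did. At 5 CPM the cAMP list (-0.047) no longer stood apart. With no minimum this held for the cAMP (-0.055), protease (-0.043), G protein (0.052) and housekeeping (-0.019) lists. With unmatched random lists it held for the TGF-beta (-0.047), ribosomal protein (-0.0068), protease (-0.069) and housekeeping (-0.019) lists, and the circadian list (-0.076) stood apart. Subtracting the abundance trend ended it for the cAMP list (-0.054) and gave it to the S phase (0.046) and mesenchymal (-0.043) lists. Subtracting the GC and length trends ended it for the cAMP (-0.054), TGF-beta (-0.023), ribosomal protein (0.013) and housekeeping (-0.0059) lists and gave it to ribosome biogenesis (0.056). Without shared members the cAMP list (-0.047) lost it. Matching on GC content ended it for the ribosomal protein (-0.0068) and housekeeping (-0.019) lists and gave it to ribosome biogenesis (0.037). Another random draw moved the cAMP list (-0.069) inside and the mesenchymal list (-0.029) outside. Apart from the use of fewer or more genes at another minimum, the cause was not tested.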

Other observations

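The tests of the same library sequenced 2 times, of PGE2 made by the cells themselves, of a culture difference and all of those on Lars2 were chosen after the result was seen, as were the noncoding RNA classes. The long noncoding RNA Malat1 had 468674 and 411935 counts (log2 ratio -0.25, -0.26 to -0.24) and Neat1, the scaffold RNA of paraspeckles and its neighbor on chromosome 19, had 9489 and 7202 (-0.46, -0.51 to -0.42). Of 185 tested long noncoding RNA genes 110 had a ratio below 1, with a median of -0.064 at percentile 1.2, and of -0.078 at percentile 0.15 after subtraction of trends on GC content and length. The 19 small nucleolar and Cajal body RNA genes had a median of -0.17 at percentile 3.44, inside the central 95%, and of -0.094 at percentile 17.2 after the same subtraction.

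Genes of ribosome biogenesis had a median of 0.037 over 30 members, at percentile 95.9. The nucleolar genes Npm1 (log2 ratio 0.15, 0.13 to 0.18), Nop58 (0.16, 0.10 to 0.22) and Dkc1 (0.12, 0.04 to 0.20) were among the 5 members with an interval above 1, and none had an interval below it. Krt6a, a stress-related keratin, had a log2 ratio of 0.54, and the ribonuclease gene Zc3h12a, which limits inflammatory transcripts, one of -0.59. Egr1 (-0.30, -0.57 to -0.03) and Ier3 (-0.22, -0.37 to -0.07) of the immediate early list were lower in the treated library and Klf6 (0.08, 0.04 to 0.12) and Dusp6 (0.09, 0.0089 to 0.18) higher, while that list's median of -0.022 was at percentile 20.5.

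Few genes differed 2-fold between the libraries. The tables argue against a lack of depth, because the interval excluded a 2-fold difference in both directions for 92.4% of the tested genes. They also argue against a plain split of the reads of 1 library. Genes with at least 3000 counts had a mean chi-square of 4.37, without Lars2, Rn45s, Malat1 and Neat1. Simulated splits of 1 library gave 0.946 to 1.06. The splits held counting error alone, so 2 runs or preparations of the same RNA that differ slightly are not excluded. In total 1396 genes had an interval that excluded 1, against 451 to 542 in simulated pairs with counting error alone. With a coefficient of variation of 2.5% added between libraries the range was 1304 to 1418. That setting is near the spread beyond counting error of genes with at least 1000 counts in these same libraries, so the match is not an independent check. A candidate explanation that stays open is that the cells already make PGE2, since no measurement of the prostaglandin is used here. Ptgs2 was at 4133 CPM in the untreated library. Of the synthase genes given above, Ptges did not reach 1 CPM in either library, while Ptges3 was abundant. A response that had passed by 6 h also stays open and was not tested.

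Lars2 and Rn45s had lower counts in the treated library, by log2 ratios of -2.13 and -0.78. The tables argue against a lower expression of mitochondrial aminoacyl-tRNA synthetases as a class, because the other 16 had a median log2 ratio of 0.018 and ratios from -0.22 to 0.29. The Lars2 transcripts of GENCODE release M21 shared 0 sequences of 20 bases with 18S or mitochondrial ribosomal RNA. This argues against reads of those RNAs assigned to Lars2 only if the same transcripts were counted. The annotation used for the counting is not given. Reads of 28S ribosomal RNA may still be involved, as Lars2 was 33.5 times as abundant as the next gene of the class in the untreated library and 7.81 times in the treated library, but the 28S sequence was not used here, so this and an effect of PGE2 on Lars2 itself cannot be told apart.

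The higher median of the G2 and M phase genes was also 0.086 after subtraction of the GC content and length trends, 0.085 after subtraction of the abundance trend and 0.085 without the 5 members with the highest ratios, above all random lists each time. These values argue against either trend, or a few members, as the whole cause. A culture or cell cycle difference between the dishes that has nothing to do with the treatment could give the same pattern. The S phase list had a positive median of 0.038, but at percentile 96.6 it did not stand apart from the random lists. An effect of PGE2 could give such a median as well, so it does not decide between these causes. With 1 library per group a culture or cell cycle difference cannot be told apart from an effect of PGE2.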
